A study of Drosophila melanogaster with 4 samples.

How the data were processed

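Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on wandering larvae of the third instar of Drosophila melanogaster. The larvae carried a GFP-tagged transgene of lola (longitudinals lacking), which encodes a family of BTB zinc-finger transcription factors. The series title names the tagged protein lola-PI, and the strain and transgene labels read lola-RI. There were 2 libraries precipitated with an anti-GFP antibody and 2 libraries of input DNA, all from the tagged strain. Samples were assigned to these groups from their titles. The labels give the sex of the larvae as unknown.

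The deposited data were 1 peak list for the whole series. Its columns are chromosome, start, end and a peak score. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2, without a role or order for each, and the BDGP5 build. Per the file headers, coordinates are on FlyBase release 5. Whether the libraries were pooled before peak calling, and which threshold was applied, is not given in the sources used here. The list gives no value per library, so the depth is unknown and no replicate error could be attached to any value. Other deposited values, the start and end of each peak, were taken as they stand (1-based).

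The peak score was deposited by the authors without a stated scale. The 2639 scores took 781 distinct values. The 38 values held by at least 18 peaks formed a ladder, and its mean step widened from 0.229 below a score of 10 to 0.288 between 15 and 16.25. A fold or a count on a linear scale would have even steps, and a −log10 p-value of counts has widening ones. The score was therefore used in the comparisons only to rank, filter and describe peaks, and no fold enrichment was derived from it. One test in the closing section, on X copy number, scales scores by a factor and so treats them as proportional to depth, a simplification that the widening steps argue against.

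Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The planned tests, gene lists, motifs and alternatives were fixed before the data were examined, and those added later are named as such. The gene table at hand was on release 6, which differs from the build of the peaks, and no release 5 genome was used here. Planned analyses of promoters, annotation classes, peak height at promoters, gene lists, motifs and the lola locus were therefore not run, and no peak was assigned to a gene. Under the rule for naming items, the 10 highest peaks by score are given by position.

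Peaks per chromosome arm were compared with expectation from arm length by a two-sided Monte Carlo test with 100000 multinomial draws and Benjamini-Hochberg adjustment over the 6 main arms. The plan called for full arm lengths. The end of the last peak on each arm was used in their place, which is a lower bound of the length. Because peaks cluster, the draws understate the spread. Arms were for that reason also compared over complete 1-Mb bins by permutation tests with 100000 resamples, a comparison chosen after seeing the data. Clustering was tested against 1000 uniform placements of as many points on each arm. Scores and widths were compared by two-sided permutation tests of the difference of medians. Exact 95% Poisson and binomial intervals cover counting error only. Peaks are not biological replicates, so all tests describe this list. The tests were checked on simulated data with 2577 peaks. The arm test recovered both of 2 changed arms and made a call in 6 of 200 simulations without a change, and the clustering test recovered the clustered set and made a call in 2 of 50 uniform sets. The arm simulations drew peaks independently, as the test assumes, so they do not show its error rate for clustered peaks.

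Alternatives were the 1322 and the 660 highest-scoring peaks (those at or above the median and the upper quartile), merging peaks within 500 bp, and main arms only. Added after seeing the data were other bin sizes, another measure of arm length, leaving out X (alone and together with the higher score limits), and leaving out the narrowest peaks.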

Results

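The series asked where GFP-tagged Lola-PI occupied chromatin in whole wandering larvae of the third instar. The design sets 2 ChIP libraries beside 2 input libraries, and the authors' peak calls were deposited as 1 list of 2639 peaks. Of these, 2577 peaks (97.7%) lay on the main chromosome arms, 53 on the Het, U and Uextra sequences and 9 on the mitochondrial genome. The Het sequences hold heterochromatin assigned to an arm, and U and Uextra hold sequence not placed on any arm. Peaks covered 882 kb in all. The median width was 290 bp, with quartiles of 234 and 385 bp, and 86 peaks had the minimum width of 201 bp. All values below come from this list, without replicates and at unknown depth, and every score is the authors' own.

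The first comparison was between chromosome arms. The X chromosome carried far fewer peaks than the large autosomal arms, and the small, largely heterochromatic chromosome 4 carried more. X held 146 peaks over 21.5 Mb, or 6.79 per Mb (95% exact Poisson interval 5.73 to 7.99). The arms 2L, 2R, 3L and 3R together held 2377 peaks over 96.3 Mb, or 24.7 per Mb. The density on X was thus 0.28 times that of the large autosomal arms (95% interval 0.23 to 0.33). Chromosome 4 held 54 peaks over 1.32 Mb, or 41.0 per Mb (95% interval 30.8 to 53.5), which was 1.66 times the density of the large arms (95% interval 1.24 to 2.18).

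Against the share expected from the length of all 6 arms, X held 0.31 times as many peaks (Monte Carlo draws from the exact multinomial distribution, adjusted p = 6e-05). In the same exact multinomial test chromosome 4 held 1.90 times as many (adjusted p = 8e-05). The corresponding ratios by exact multinomial draws were 1.22 for 2R (adjusted p = 6e-05), 1.16 for 3R (adjusted p = 9e-05), 1.14 for 3L (adjusted p = 0.0005) and 1.05 for 2L (adjusted p = 0.18). Over all peaks, the calls for the large arms rested on the low count of X. With X left out, none of the 4 large arms passed the test and chromosome 4 still did (ratio 1.65, exact multinomial draws, adjusted p = 0.005). Among the 660 highest-scoring peaks of the list the contrast was wider, with a ratio of 0.19 for X and 2.90 for chromosome 4. The ratio of 2R rose to 1.47 among them, and with X left out it still passed (ratio 1.25, exact multinomial draws, adjusted p = 0.0054). These draws ignore the clustering of peaks and so understate the spread, and no bin comparison was made for the 660 peaks.

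**Figure D1:**
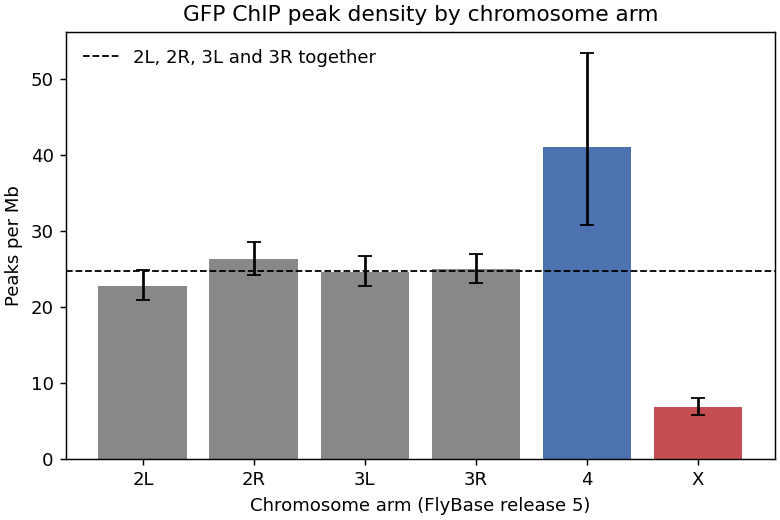
Peaks per Mb on each main arm, with the arm length taken up to the end of the last peak. Bars are densities, error bars are 95% exact Poisson intervals (counting error only), and the dashed line is the density of 2L, 2R, 3L and 3R together, 24.7 per Mb. X lies at 6.79 per Mb and chromosome 4 at 41.0 per Mb.

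The deficit on X extended along the chromosome. Its 21 complete 1-Mb bins held 6.81 ± 3.92 peaks (mean ± SD over bins), and the 93 bins of the large autosomal arms held 24.9 ± 9.55. The difference exceeded the spread between bins (two-sided permutation test, p = 1e-05, the smallest that the resamples can give). The fullest bin of X held 16 peaks and the emptiest 2. Only 2 of the 93 autosomal bins held as few peaks as the X mean. Bin means of the 4 large arms ran from 22.95 on 2L to 26.7 on 2R, and their spread was within that of shuffled bins (permutation p = 0.62). Chromosome 4 was less extreme on this scale. Of 912 overlapping windows of the same length on the large arms, 35 (3.84%) held at least 54 peaks, and the fullest held 70.

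**Figure D2:**
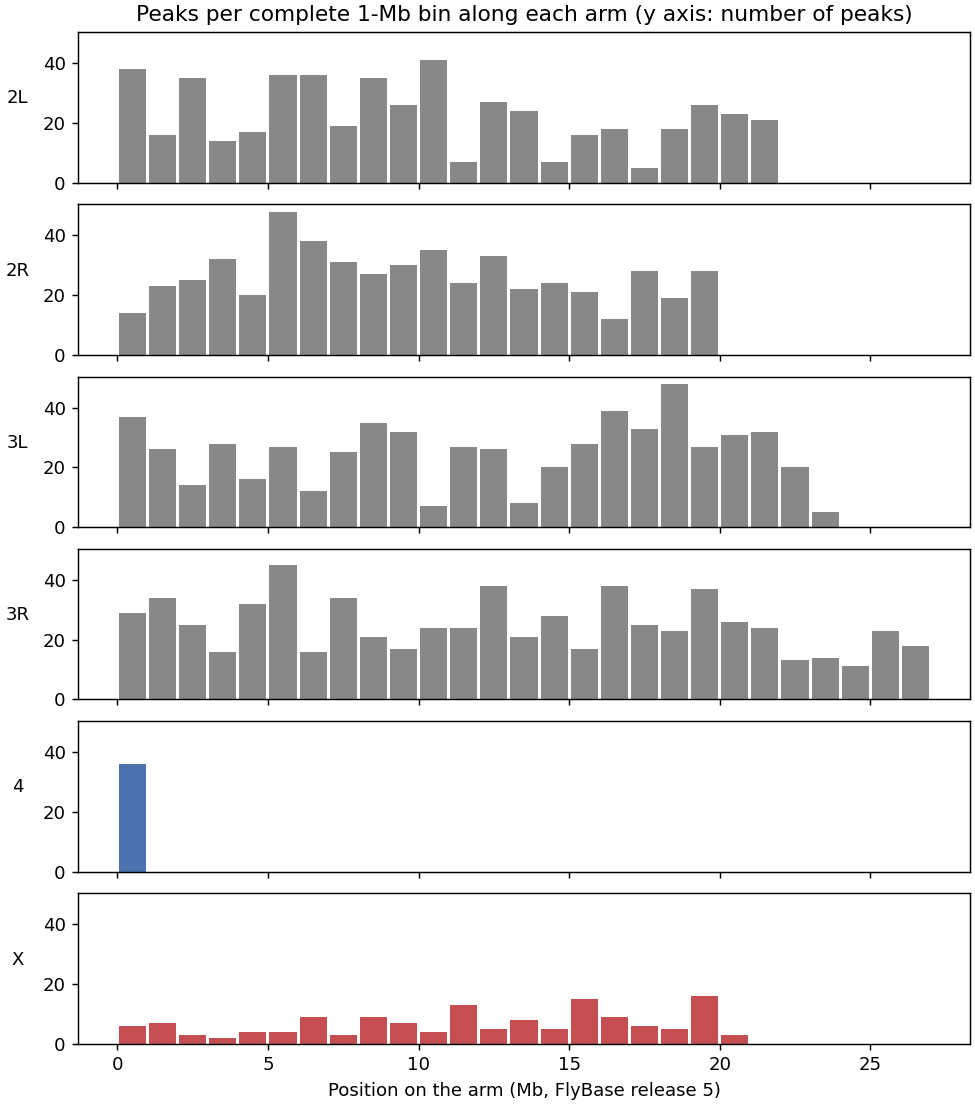
Number of peaks in each complete 1-Mb bin (y axis) against position in Mb on FlyBase release 5 (x axis), with 1 panel per arm and a shared y axis. Bins of X, in red, hold 2 to 16 peaks, and bins of the large arms, in grey, hold 5 to 48.

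Peaks on X also had lower scores. Their median score was 11.9, against 13.2 on the other main arms (permutation test, adjusted p = 0.028). Peaks on 2R scored higher than the rest, with a median of 13.7 against 12.9 (permutation test, adjusted p = 0.028). Chromosome 4 had a median score of 13.98 against 12.95 elsewhere, a difference that did not pass (permutation test, adjusted p = 0.43). The median width on X was 270 bp against 292 bp on the other arms (permutation test, adjusted p = 0.25), and no arm passed for width. Across all 2639 peaks, wider peaks had higher scores (Spearman's rho = 0.44, permutation p = 1e-05, the smallest that the resamples can give). Width and score come from the same peak calls, so the calling itself may build in this relation.

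The second question was how peaks were spaced. Neighbouring peaks lay closer together than uniform placement on the same arms gave. The median distance between neighbouring midpoints was 11595 bp over 2571 gaps, against 29241 bp in the placements (95% of placements between 28029 and 30411 bp), a ratio of 0.40 (permutation p = 0.002, the smallest that 1000 placements can give). Among the 660 highest-scoring peaks the ratio was 0.71 (permutation p = 0.002). With peaks within 500 bp merged, the ratio was 0.51 (permutation p = 0.002). In the unmerged list, pairs closer than 1 kb numbered 357, against a median of 62 in the placements. No count of these pairs after merging is given, so single regions split in the calling may be among them. Every one of the 6 main arms passed the permutation test of the median gap on its own, with ratios from 0.31 on 2L to 0.52 on X (adjusted p = 0.002 each). On X the median gap was 52525 bp, against 101884 bp under uniform placement.

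The most crowded 100-kb stretches, picked from the list for their counts, lay on autosomes. On 2L, 18 peaks lay between 5975030 and 6074688, with a median score of 13.1. On 2R, 18 peaks lay between 6362588 and 6456987, with a median score of 18.8. On 3L, 17 peaks lay between 18783744 and 18883504, and on 3R, 17 peaks lay between 12012939 and 12107488. Then followed 2L from 4968182 to 5060595, with 15 peaks. Uniform placements held 10 peaks in their fullest stretch at the median and 17 at the most, and none of the 1000 reached 18. The transgene adds copies of lola sequence, which can change read depth there. Whether any of these stretches holds lola was not analysed here, and the 2R stretch in particular would need that check. The part of that stretch in the higher scores and ratios of 2R was not tested.

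Scores ran from 6.27 to 253, with a median of 13.2 and quartiles of 10.6 and 17.0. The highest peak lay on 3L from 18018910 to 18020026, was 1117 bp wide and scored 253. The next was on 3R from 58080 to 58848, with a score of 132. Ranks 3 to 5 lay outside the main arms, on 2RHet from 471633 to 472342 (score 108) and from 369900 to 370612 (score 107), and on 3LHet from 1396453 to 1397123 (score 107). Rank 6 was on 3R from 27283607 to 27284227 (score 106), and rank 7, the highest on X, lay from 5640147 to 5640895 (score 97.1). The remaining ranks were 3R from 15686497 to 15687939 (score 86.9), 2R from 1181232 to 1181721 (score 82.5) and 3R from 8537936 to 8538792 (score 81.0).

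**Figure D3:**
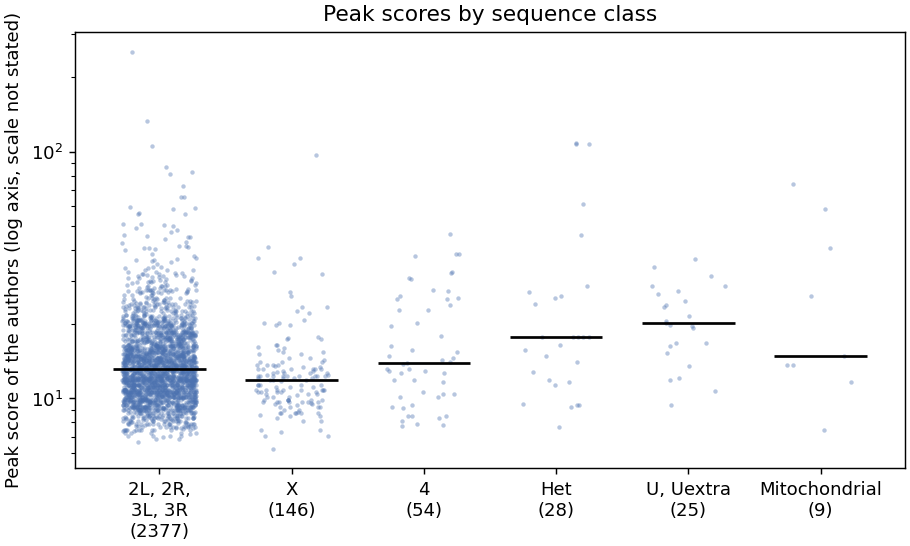
Peak scores of the authors on a log axis, by sequence class, with the number of peaks in brackets. Points are single peaks and lines are medians, at 11.9 on X, 13.2 on the large autosomal arms, 17.7 on the Het sequences, 20.2 on U and Uextra, and 14.8 on the mitochondrial genome.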

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

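Of the tests in this part, those on empty X regions and on shared score values were chosen after the result had been seen, as was the limit of the 26 highest peaks, for which counts are given without a test. No biological explanation was tested, since the samples form only a ChIP and an input group from 1 strain.

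The comparisons of arms left out 9 peaks on the mitochondrial genome. They covered 28.5% of the 12541 bp up to the end of the last of them, against 0.72% on the main arms. The widest ran from 1398 to 2642 and scored 73.8, and the next highest ran from 4896 to 5453 with a score of 58.4. Many mitochondrial genomes per cell raise read depth and could so raise scores without any binding by Lola. The median score was 14.8, which was 1.78 above that of the main arms (permutation p = 0.3), which does not decide it. The scores of 73.8 and 58.4 put 2 of the 9 among the 26 highest peaks of the list. Depth and antibody background, for which no untagged strain was analysed here, both stay open.

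A further 53 peaks on the Het, U and Uextra sequences were also outside the comparisons of arms. Their median score was 17.7 against 13.0 on the main arms (permutation p = 5e-05, the smallest that 20000 resamples can give). Of the 26 highest peaks in the list, 4 were among these 53 (7.55%) and 20 among the 2577 of the main arms (0.78%). All 4 lay on the Het sequences, and the highest score on U and Uextra was 36.6. One candidate explanation is sequence present in more copies than assembled. U and Uextra, which collect unplaced sequence, had a median score 2.52 above that of the Het sequences (permutation p = 0.35), and this test could not tell.

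The low peak density on X has technical explanations that the tables leave open. A few X regions without peaks were tested by the median X bin, which held 6 peaks, below the autosomal lower quartile of 18. The low X total fixes that outcome, so it decides nothing. Every complete 1-Mb bin of X held at least 2 peaks and the fullest held 16, so the deficit was not confined to empty 1-Mb bins. Lower X copy number in a pool that holds males could lower X scores: multiplying autosomal scores by 0.60 (95% interval 0.57 to 0.64) would equalise the densities at the median X score, and factors of 0.55 and 0.59 did so at the other quartiles. All 3 intervals lie above the 0.5 of an all-male pool and below the 0.75 of equal sexes. Those bounds apply to depth, so the score factors give no sex ratio. The factors treat scores as proportional to depth, which the widening steps of the score argue against, and the sex ratio is not given, so this test cannot tell. Between scores of 8 and 16, 79.1% of X peaks sat on the 30 score values most common on the large arms. The share was 54.5% for the peaks of those arms (Fisher's exact test, p = 1.6e-07). Those 30 values made up 3.75% of the possible score values in that range. One background level for X and the autosomes predicts such shared values, and this prediction was met. Fisher's test itself only compares the shares, and the 30 values were picked from the large arms. The effect of such a level on X scores was not measured. Fewer Lola-PI sites on X remains an untested hypothesis.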

How the results depend on the processing

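No paired analysis was possible because the deposited list holds no value per library, and for the same reason no replicate could be left out. Settings that need annotated gene starts or sequence were not run. By construction, the peaks at or above the median score numbered 1322 and those at or above the upper quartile 660, and merging within 500 bp left 2343. The deficit of X, the excess of chromosome 4, the short gaps and the relation of width to score kept their direction and passed their tests under each alternative tried for them. For chromosome 4 these tests were all multinomial draws, which understate the spread. Among windows of its length on the large arms, 35 of 912 (3.84%) held at least as many peaks, so its excess is less firm than the deficit of X. The observed over expected ratio ranged from 0.19 to 0.34 for X and from 1.65 to 2.90 for chromosome 4, the gap ratio from 0.40 to 0.71, and Spearman's rho from 0.43 to 0.44. With X left out, a choice made after seeing the data, the ratio fell below 1 for 2L (0.92) and 3L (0.99) and to 1.06 and 1.00 for 2R and 3R, because X sets the expectation of the other arms, and 2R and 3R no longer passed. With X left out and only the 1322 highest-scoring peaks kept, the ratios were 0.90 for 2L, 0.95 for 3L and 0.99 for 3R, and 1.13 for 2R, which passed (exact multinomial draws, adjusted p = 0.048). With the 660 highest they were 0.86, 0.93 and 0.92, and 1.25 for 2R (exact multinomial draws, adjusted p = 0.0054). The draws ignore the clustering of peaks, and no bin comparison was made for the 1322 or the 660. With X kept, the ratio of 2R was 1.33 among the 1322 and 1.47 among the 660. The ratio of 3L also missed the threshold among the 1322 highest-scoring peaks, and those of 3L and 3R among the 660. Of the 53 peaks on the Het, U and Uextra sequences 31 were among those 660, as were 4 of the 9 mitochondrial peaks. The unknown depth limits any statement about regions without a peak.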

Other observations

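Peak counts near the centromere varied by arm. The bin nearest the centromere held 29 peaks on 3R and 21 on 2L, but 14 on 2R, 5 on 3L and 3 on X. The hypothesis that peaks thin out towards the centromere, tested after seeing the bins, was not borne out: over the bins of the 5 large arms, X included, bin counts relative to the arm mean had a Spearman's rho of 0.11 with distance from the telomere (permutation p = 0.25), and none of the 5 arms passed on its own (lowest adjusted p = 0.34, for 3R).

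Although peaks crowd together, no likeness of neighbouring scores was detected over all neighbours on the main arms. Crowded stretches were not tested on their own. The hypothesis that neighbouring peaks have like scores, stated before the test, was not borne out. The rank correlation of neighbouring scores on the main arms was 0.032, inside the middle 95% of scores shuffled within arms (-0.032 to 0.043, permutation p = 0.19).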
